A study of Populus trichocarpa
Populus deltoides with 74 samples.

How the data were processed

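RNA from poplar buds and shoot tips was hybridised to an oligonucleotide array in the wells of 96-well plates, with Cy5 as the only label. The 74 arrays came from 37 RNA isolations in 19 groups, and each isolation was hybridised to 2 wells. Each group had 2 isolations except the June shoot tips of age 5, which had 1. The design text calls the isolations biological replicates. Nothing in the sources says that they came from separate trees, so each p-value measures spread between isolations.

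The deposited table holds a single value per oligo and array. The values ran from 1.10 to 16.25, and they were read as log2 intensities from this range, since the deposited description gives no log base. Scanner settings, background correction, any earlier normalization and the handling of duplicate spots are not given in the sources used here. The table covered 217 oligos, of which 34 carried a gene-like name and 183 only a clone name or accession. No chromosome position came with the IDs. The printed control oligos could not be told from the poplar oligos by ID, and every oligo of the table was tested. Missing values made up 1.35% of the table (216 values) and stayed missing. An array gave a value for 206 to 217 oligos. Signal over background cannot be judged without background values, and the small number of oligos and isolations limits the precision.

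Array medians lay between 8.05 and 8.79, a range of 0.735 that exceeded the 0.2 allowed for use without further scaling, so the arrays were quantile-normalized. Under this scaling the brightest oligo of each complete array takes almost the same value, which bounds the differences of the brightest oligos. The 2 wells of an isolation were then averaged. A linear model with a mean for each of the 19 groups was fitted to the 37 isolations with limma 3.58.1 in R 4.3.3, leaving 18 residual degrees of freedom. Each comparison is a contrast of that model, group means weigh equally, and all tests are two-sided moderated tests of limma. P-values were adjusted by the Benjamini-Hochberg method over the 217 oligos of each comparison, and an adjusted p under 0.05 counted as a call.

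The groupings, comparisons, gene lists, tests and most other settings were fixed before the data were examined. So was the rule for naming genes. In the comparisons of floral with vegetative buds, of age across organs, of basal with upper shoot tips and of June with May, it takes the 12 largest rises and the 12 largest falls among called oligos whose matched differences all share a sign, and up to 4 members of each list. In the other comparisons it takes the 4 largest rises and the 4 largest falls. Where fewer than 5 passed, the 5 smallest p-values are given as values that did not pass. Oligos known only by a clone name are limited to 2 that rose and 2 that fell. Names chosen outside this rule are marked as chosen after their values were seen. A vegetative bud group and a floral bud group of age 6 have no stated sex, another pair is labelled male, and "upper" shoot tips are those not labelled basal. Counts of isolations above or below a mean use the pooled mean of the other side, not matched by organ, month, age or tree type.

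Gene lists were matched to the IDs by symbol. Floral meristem identity had 3 measured members, light receptors 4, and floral organ identity, photoperiod promotion of flowering and gibberellin 2 each. The remaining lists, on floral repression, autonomous and vernalization pathways, the clock, chromatin, vegetative phase change, shoot meristem, axillary branching, dormancy and cold, photosynthetic leaf, secondary wall and housekeeping, had 0 members among the named IDs. A list of 8 auxin transport and response genes was made after the IDs were seen. Lists with at least 3 members were tested with camera in limma, with a preset correlation of 0.01 and with an estimated correlation, over the 213 oligos complete in every isolation. The array itself carries genes picked for flowering and maturation work, so the other oligos are not a neutral background.

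Wells of an isolation correlated at a median of 0.966, isolations of a group at 0.956 and arrays of different groups at 0.848. The median residual SD between isolations was 0.30. Differences between the 2 wells of an isolation sorted the isolations into 5 sets of 7, 10, 9, 2 and 9 isolations, called hybridisation sets here. The labels give no plate or date, and these sets were found after the data were examined. Isolation b of the May basal tips of age 5 sits least firmly, with a mean correlation of 0.109 to its own set and of 0.0781 to the set of the May upper tips. With it moved to the latter, 9 of 17 comparisons could still be fitted with the set as a term, and basal against upper tips, the basal difference by month, June against May and vegetative buds against May tips could not. Values with the set as a term in those 4 rest on this placement. The other settings tried were the values as deposited, arrays centred on their median, leaving out the lowest 25% of oligos by signal, wells as separate arrays, a fit to the compared groups alone, a trended robust variance, the isolation letter as a block, a slope per year of age and leaving out each isolation in turn. Settings with the hybridisation sets and with subsets of ages were added after the data were seen.

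The procedure was tested on simulated data of the same layout, with 20 oligos changed at each of 3 sizes. Each comparison was simulated a single time. Apart from these changes the isolations varied around a common mean per oligo, without hybridisation sets, so the effect of sets was not covered. For floral against vegetative buds it called 30% of oligos changed by 0.5, 75% of those changed by 1 and 95% of those changed by 2, with 2 of 157 unchanged oligos called. For June against May it called 50%, 80% and 100%, with 14 of 157 unchanged oligos called, and the cause of the larger number there was not tested.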

Results

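Transcript levels were measured for 217 oligos in poplar buds and shoot tips of wild-type trees aged 1, 2, 5 and 6 years, with both Populus trichocarpa and Populus deltoides named as the organism. Lateral vegetative buds were sampled at all 4 ages, and male vegetative buds and both kinds of floral buds at age 6. Shoot tips labelled female were sampled in May and June at all 4 ages, and basal shoot tips in both months at ages 5 and 6. Each of the 19 groups had 2 RNA isolations except the June shoot tips of age 5, with 1. Values below are quantile-normalized log2 intensities, differences carry the standard error (SE) from limma, and adjusted p-values are over all 217 oligos.

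The first question was which genes distinguish buds that carry flowers from vegetative buds of the same age. Among oligos with a gene-like name, the genes of flower identity rose most. PTAP1-2A, an APETALA1 homolog, averaged 14.02 in floral buds and 8.43 in vegetative buds, a difference of 5.59 ± 0.52 (SE, n = 4 and 4 isolations, adjusted p = 7.4e-09). PTAG1 and PTAG2, homologs of the stamen and carpel gene AGAMOUS, rose by 5.31 ± 0.41 (adjusted p = 3.9e-10) and 4.61 ± 0.31 (adjusted p = 3.2e-11). PTAP1-1B rose by 3.39 ± 0.42, the DEFICIENS homolog PTD by 2.50 ± 0.30 and the LEAFY homolog PTLF by 1.26 ± 0.16 (adjusted p = 9.6e-07, 5.9e-07 and 1.6e-06). For each of these 6 genes all 4 floral isolations lay above the vegetative mean. PTAP1-2A reached 14.26 with an SD of 0 in male floral buds, the top value that quantile scaling gives, which is not a measured ceiling. The highest deposited values on these arrays were 13.66 to 13.77, so scaling raised PTAP1-2A there and the size of its rise depends on it.

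Other regulators moved both ways. The auxin response gene PttIAA6 fell by 2.79 ± 0.24 (adjusted p = 1.9e-09), while PttIAA1 rose by 0.81 ± 0.13 (adjusted p = 3.0e-05). Among auxin efflux carriers PTTPIN1 rose by 1.12 ± 0.27 and PTTPIN2 by 1.22 ± 0.43, whereas PTTPIN3 fell by 1.31 ± 0.32 (adjusted p = 0.00266, 0.0348 and 0.00341). The CONSTANS homolog PTCO11 rose by 0.52 ± 0.15 (adjusted p = 0.0127). R-AP2 fell by 0.70 ± 0.14, PTBF1 by 0.73 ± 0.23, HB2 by 0.45 ± 0.16, and PCEN-L, a relative of the inflorescence gene CENTRORADIALIS, by 0.56 ± 0.20 (adjusted p = 0.0004, 0.0199, 0.0354 and 0.0363). Among oligos known only by clone name, V059D02 rose by 4.92 ± 0.56 and M129E09 by 4.61 ± 0.31, while B016P21Um fell by 3.50 ± 0.23 and A010P29U by 2.24 ± 0.30. For PTBF1 and HB2, 3 of 4 floral isolations lay below the vegetative mean. The call of PTTPIN2 was lost on leaving out any of 7 of the 8 isolations, and those of PTBF1, PCEN-L and HB2 on leaving out any of 5, with adjusted p up to 0.110, 0.134, 0.118 and 0.210. PTCO11 lost its call when wells entered as separate arrays, with an adjusted p of 0.0614. Among the other settings fixed beforehand PTBF1 and HB2 lost theirs in 2 and PCEN-L in 3, with adjusted p up to 0.0752, 0.404 and 0.137. With the hybridisation set as a fixed term PTTPIN2 (1.31 ± 0.49) and HB2 (-0.36 ± 0.19) did not pass (adjusted p = 0.0594 and 0.185), nor did PTBF1 within a single set (-0.80 ± 0.25, adjusted p = 0.0735). The differences of PTTPIN2 and PTBF1 were no smaller there, with a larger SE.

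By list, all 3 floral meristem identity genes rose, which is also the count adjusted over the list alone. Camera gave this list an adjusted p of 0.000718 with the preset correlation and an adjusted p of 0.0193 with an estimated correlation. Both floral organ identity genes rose, 2 of 2 adjusted over the list alone. Of the photoperiod genes PTCO11 rose and PTCO12 differed by 0.28 ± 0.17 (adjusted p = 0.23, and 0.0221 in the values as deposited), 1 of 2 adjusted over the list alone. Among the 4 light receptors 0 passed limma's test, over all oligos and adjusted over the list alone, although PHYA differed by 0.83 ± 0.32 (adjusted p = 0.053, and 0.0282 in the values as deposited), and across all oligos 88 had an unadjusted p under 0.05. Camera gave the light receptors an adjusted p of 0.825, and of 0.869 with an estimated correlation. Of the gibberellin genes, GA20-OX differed by 0.54 ± 0.40 and PttGA2-OX by -0.46 ± 0.26, and neither passed. In all, 64 oligos were called, 21 higher and 43 lower in floral buds. This split depended on scaling, with 36 higher and 19 lower in the values as deposited and 19 higher and 33 lower after median centring, while the median oligo moved from -0.07 to 0.12 and -0.10.

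**Figure D1:**
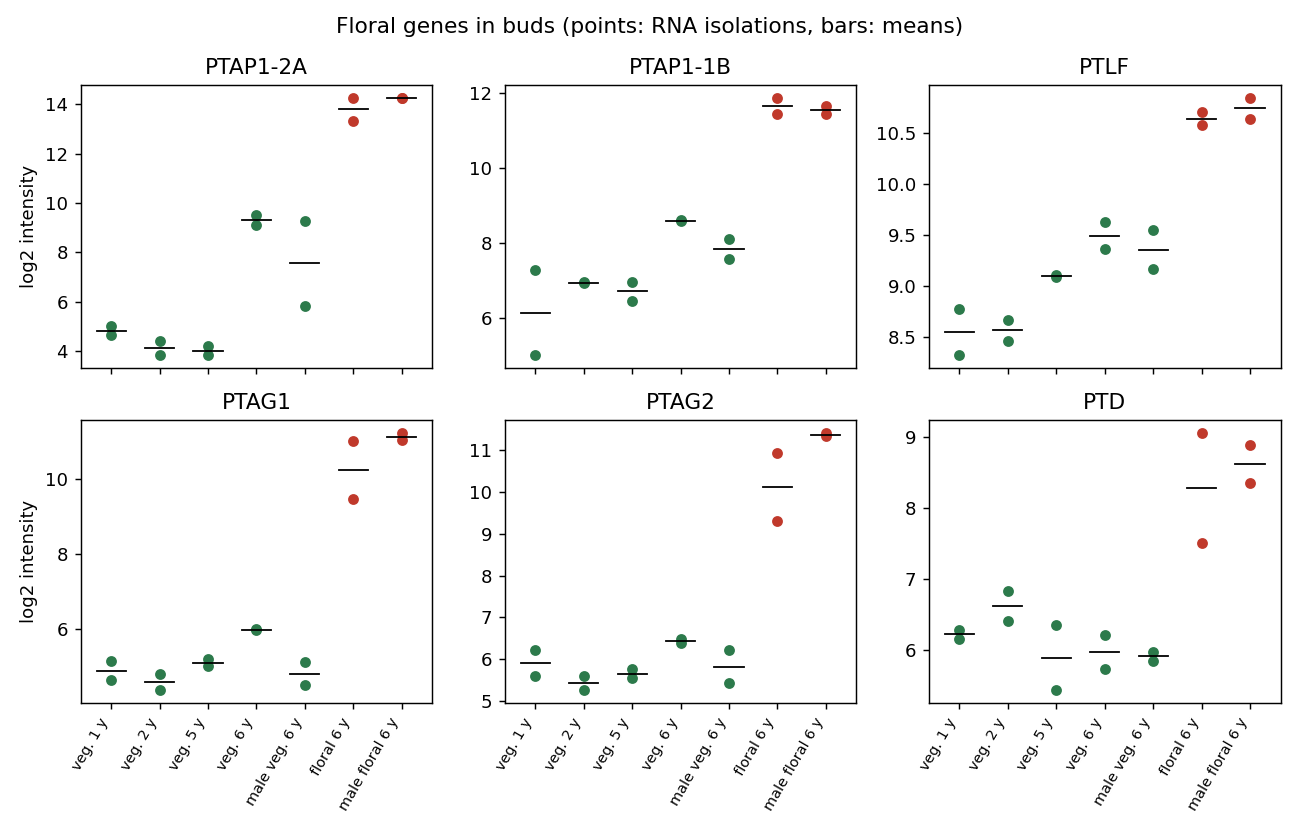
Log2 intensity (vertical axes) of 6 floral genes in 7 bud groups (horizontal axes), with each point an RNA isolation and each bar a group mean. PTAG1 lies at 10.25 and 11.14 in the floral groups and at or below 5.97 in the vegetative groups, and PTAP1-2A is at 9.31 in vegetative buds of age 6 against 4.03 at age 5.

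The same floral contrast was made in each tree type, those of unstated sex and those labelled male. PTAG2 rose by 5.54 ± 0.43 in male trees and PTAG1 by 6.35 ± 0.58, against 3.68 ± 0.43 and 4.28 ± 0.58 in trees of unstated sex. The differences of these differences, 1.86 ± 0.61 for PTAG2, 2.07 ± 0.82 for PTAG1, 2.21 ± 1.04 for PTAP1-2A, 1.80 ± 0.75 for PTIR1 and -0.82 ± 0.28 for R-AP2, did not pass (adjusted p = 0.381, 0.411, 0.549, 0.411 and 0.381). Limma called 0 oligos for this difference, with 19 at an unadjusted p under 0.05. Adjusted over the list alone, 2 of 2 floral organ identity genes, PTAG1 and PTAG2, passed for this difference. The vegetative buds enter it as well as the floral buds. Male minus unstated, the mean of PTAG1 and PTAG2 was 1.07 in floral and -0.90 in vegetative buds, with neither gene called over all oligos. For the 3 floral meristem identity genes the same means were 0.15 and -0.88, so their gap lay mostly in the vegetative buds. The contrast called 43 oligos in male trees and 34 in the others, and 26 were called in both, all 26 in the same direction, where 3.57 would be expected by chance. Across the 217 oligos, which are not independent replicates, both sets of differences correlated with a Pearson r of 0.891 and a Spearman rho of 0.708. Leaving out isolation a of the floral buds or isolation b of the vegetative buds of unstated sex gave 2 calls, and leaving out isolation a of the male vegetative buds gave 1.

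Male buds were also set against buds of unstated sex. In vegetative buds R-AP2 was higher in male trees by 0.86 ± 0.20 (n = 2 and 2 isolations, adjusted p = 0.0204), and the clone oligos UA13CPF12 and V002G11 by 2.00 ± 0.36 and 1.17 ± 0.21 (adjusted p = 0.00199 for each). Here 5 oligos were called, all 5 higher in male buds, but 0 under the values as deposited, after median centring, within a single hybridisation set, or without isolation b of the male vegetative buds. In the last of these fits R-AP2 (not called in 3 of 4 fits without an isolation) no longer passed, and UA13CPF12 and V002G11 had an adjusted p of 0.0702. Within the set R-AP2 was at 1.02 ± 0.21, UA13CPF12 at 2.07 ± 0.55 and V002G11 at 1.21 ± 0.21 (adjusted p = 0.191, 0.226 and 0.191), no smaller than before, in a fit to fewer isolations. In floral buds limma called 0 oligos, with 25 at an unadjusted p under 0.05. The smallest adjusted p there was 0.287, shared by PTAG2 (1.24 ± 0.43), PTIR1 (1.47 ± 0.53), PttIAA1 (-0.50 ± 0.18), PTBF1 (-0.89 ± 0.33) and PTPGM (0.42 ± 0.16). Adjusted over the list alone, 1 of 2 floral organ identity genes passed there. Without isolation a of the floral buds of unstated sex 13 oligos were called.

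The next question was how levels change as trees mature, comparing ages 5 and 6 with ages 1 and 2. In vegetative buds the CONSTANS homologs fell with age, PTCO12 by 1.58 ± 0.17 and PTCO11 by 1.19 ± 0.15 (n = 4 and 4 isolations, adjusted p = 3.1e-07 and 3.0e-06). PTLF rose by 0.74 ± 0.16 (adjusted p = 0.00128), from 8.54 and 8.56 at ages 1 and 2 to 9.09 and 9.49 at ages 5 and 6. The gibberellin-inactivating enzyme gene PttGA2-OX rose by 0.82 ± 0.26 and PttIAA6 by 0.95 ± 0.24, while PttIAA1 fell by 1.20 ± 0.13 and PTBF1 by 1.82 ± 0.23 (adjusted p = 0.0191, 0.00317, 3.1e-07 and 2.4e-06). PTAP1-2A was higher by 2.18 ± 0.52 (adjusted p = 0.00227), but only 2 of the 4 older isolations lay above the younger mean. Its level was 9.31 at age 6 and 4.84, 4.13 and 4.03 at ages 1, 2 and 5, and with age 5 alone against ages 1 and 2 the difference was -0.46. The clone oligos R29F11 and UB18CPG04 rose by 2.54 ± 0.30 and 1.71 ± 0.13, while R74E10 and R26F09 fell by 1.91 ± 0.44 and 1.56 ± 0.15.

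Vegetative buds gave 64 called oligos with age, 33 higher and 31 lower, with 28 higher and 30 lower in the values as deposited and 22 higher and 34 lower after median centring. Within a single hybridisation set the count was 53, and PttIAA6 (0.87 ± 0.28, adjusted p = 0.0562) and R74E10 (-1.65 ± 0.58, adjusted p = 0.0743) did not pass, with slightly smaller differences and a larger SE. The call of PttGA2-OX was lost in 3 of the 8 fits that left out an isolation, with an adjusted p up to 0.106, and with the hybridisation set as a fixed term (0.66 ± 0.29, adjusted p = 0.114). By list, 2 of 3 floral meristem identity genes rose, 3 of 3 adjusted over the list alone, with a camera adjusted p of 0.114 and an adjusted p of 0.247 with an estimated correlation. Beside this list, the floral bud oligo M129E09 was higher at age 6 than at ages 1, 2 and 5 by 2.31 ± 0.36, PTAP1-1B by 2.00 ± 0.49 and PTAP1-2A by 4.98 ± 0.60. Both photoperiod genes fell, 2 of 2 adjusted over the list alone.

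In May shoot tips 14 oligos were called with age, 7 higher and 7 lower. R-AP2 fell by 0.47 ± 0.14 (n = 4 and 4 isolations, adjusted p = 0.0456), UB18CPG04 rose by 1.64 ± 0.13 and UB36DPH07 by 0.91 ± 0.23, and UM93TD04 and V061D11 fell by 1.54 ± 0.25 and 0.94 ± 0.24 (adjusted p = 4.2e-09, 0.0198, 0.000503 and 0.0198). R-AP2 lost its call in 7 of the 8 fits without an isolation and UB36DPH07 and V061D11 in 4, with adjusted p up to 0.244, 0.131 and 0.165. In the other settings fixed beforehand R-AP2 and V061D11 lost their calls in 2 of 8 and UB36DPH07 in 3 of 7, with adjusted p up to 0.168, 0.134 and 0.136. The count itself fell to 7 and 8 without isolation a or b of age 1, 3 without isolation a of age 2, 5 without isolation b of age 5, and 9 and 5 without isolation a or b of age 6.

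In June shoot tips 17 oligos were called, 8 higher and 9 lower (12 and 8 as deposited). Both isolations of age 1 form a hybridisation set of their own, so this contrast is in part one between sets. F100P70Y and R35H10 rose by 1.39 ± 0.37 and 1.27 ± 0.25, and UM43TE12 and M118F07 fell by 1.75 ± 0.18 and 1.75 ± 0.27 (n = 3 and 4 isolations, adjusted p = 0.02, 0.00314, 3.0e-07 and 0.000248). For F100P70Y 2 of 3 older isolations lay above the younger mean. Its levels were 4.84, 4.46, 7.54 and 4.54 at ages 1, 2, 5 and 6, so the difference rests on age 5, which has 1 isolation. Without that age F100P70Y was at -0.11 ± 0.40 (adjusted p = 0.879) and R35H10 at 1.16 ± 0.27 (adjusted p = 0.0137), with 21 oligos called. F100P70Y lost its call in 2 of 6 fits without an isolation, with an adjusted p up to 0.0965. It also lost it with a slope per year of age (0.0959) and in a fit to the June tips alone (0.231), where R35H10 did not pass either (0.0749). Within a single hybridisation set, which holds ages 2, 5 and 6 of the June tips, 1 oligo was called between ages 5 and 6 and age 2, and F100P70Y (1.58 ± 0.56), R35H10 (1.42 ± 0.33) and UM43TE12 (-0.93 ± 0.21) did not pass (adjusted p = 0.281, 0.128 and 0.128), of which only UM43TE12 had a smaller difference than before. The photoperiod genes PTCO12 and PTCO11 differed with age in June tips by -0.56 ± 0.19 and -0.44 ± 0.17 (adjusted p = 0.0676 and 0.111), and 2 of 2 passed adjusted over the list alone. So did 1 of 3 floral meristem identity genes, PTLF at 0.51 ± 0.18 (adjusted p = 0.0844 over all oligos). Its levels of 8.77, 8.28, 9.48 and 8.58 at ages 1, 2, 5 and 6 place this difference in the single isolation of age 5.

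Averaged over the 3 organs, 53 oligos were called with age, 24 higher and 29 lower. UB18CPG04 rose by 1.36 ± 0.08 (n = 11 and 12 isolations, adjusted p = 7.7e-12), with 11 of 11 older isolations above the younger mean, and UA13CPF12 by 0.72 ± 0.15 (8 of 11, adjusted p = 0.00145). The counts in this paragraph use a younger mean pooled over the 3 organs, so levels that differ between organs enter them. They do not show how many isolations followed age within an organ. UM93TD04 fell by 1.32 ± 0.15 (11 of 11) and UM43TE12 by 1.07 ± 0.09 (9 of 11), with adjusted p = 1.3e-06 and 1.4e-08. PTLF rose by 0.37 ± 0.10 (7 of 11, adjusted p = 0.00799), but did not pass without the June tips of age 5 (0.22 ± 0.10, adjusted p = 0.137). PTCO12 fell by 0.64 ± 0.10 (9 of 11), PTCO11 by 0.60 ± 0.09 (9 of 11) and PttIAA1 by 0.47 ± 0.08 (5 of 11), with adjusted p = 8.3e-05, 4.6e-05 and 0.000105. PTLF and PTCO12 were named as list members, since their differences did not share a sign in all 3 organs. In May tips the mean difference of the 2 photoperiod genes was 0.03. PTAP1-2A was higher by 0.88 ± 0.31 (7 of 11, adjusted p = 0.042), a call lost in 18 of 22 fits without an isolation, with an adjusted p up to 0.0997, and in 2 of 7 other settings fixed beforehand, with an adjusted p up to 0.176. It was at -0.000707 without the vegetative buds of age 6. By list, 2 of 3 floral meristem identity genes rose, 3 of 3 adjusted over the list alone, with a camera adjusted p of 0.114 and an adjusted p of 0.247 with an estimated correlation. The rise of floral bud oligos in vegetative buds of age 6, such as M129E09 by 2.31 ± 0.36, enters this mean. Both photoperiod genes fell, and among 2 floral organ identity, 4 light receptor and 2 gibberellin genes 0 passed limma's test, over all oligos and adjusted over the list alone, while 68 oligos of the array had an unadjusted p under 0.05.

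The age differences were not the same in each organ. The June tips of age 1 lie alone in their hybridisation set, so age and set differ together there. Neither the test among organs nor the mean over organs was fitted with the set as a fixed term. A moderated F test in limma for a difference among the 3 organs called 48 oligos. Among them were PTCO12 (adjusted p = 6.4e-05), PttIAA1 (0.000121), PTBF1 (0.000432), R-AP2 (0.00303), PTCO11 (0.0039), PttIAA6 (0.0067) and PTLF (0.0186), in fits to 23 isolations. UB18CPG04, chosen here after its values were seen, also differed in size between organs (adjusted p = 0.000964), rising by 0.72 ± 0.15 in June tips.

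**Figure D2:**
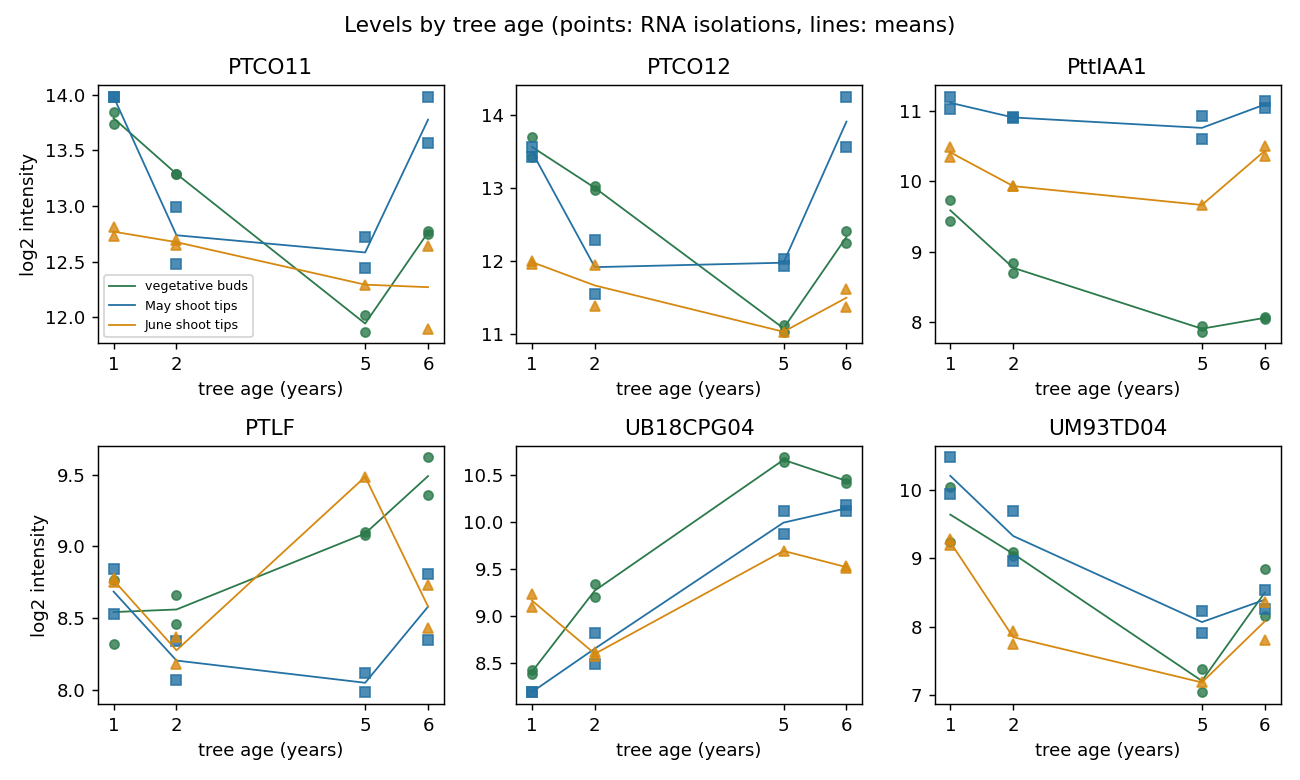
Log2 intensity (vertical axes) of 6 oligos against tree age in years (horizontal axes) in vegetative buds, May shoot tips and June shoot tips, with each point an RNA isolation and each line joining group means. UB18CPG04 goes from 8.41 at age 1 to 10.44 at age 6 in vegetative buds and from 8.19 to 10.14 in May tips, while PTCO12 in May tips lies at 13.50 and 13.91 at ages 1 and 6 and at 11.91 and 11.98 at ages 2 and 5.

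Basal shoot tips were compared with upper shoot tips of ages 5 and 6, within month and age. The auxin efflux carrier PTTPIN3 was higher in basal tips by 1.77 ± 0.24, at 11.74 against 9.97, and the cryptochrome PTCRY1D by 1.33 ± 0.13 (n = 8 and 7 isolations, adjusted p = 2.0e-06 and 1.1e-08). PTID1L1A and PTID1L3, INDETERMINATE1-like by name, rose by 1.23 ± 0.19 and 0.93 ± 0.25, PTPGM by 1.07 ± 0.09, PTCO11 by 0.92 ± 0.11, HB1 by 0.72 ± 0.15, R-AP2 by 0.67 ± 0.11 and the phytochrome PHYB2 by 0.54 ± 0.14 (adjusted p = 1.5e-05, 0.00404, 4.0e-10, 5.1e-07, 0.000402, 1.5e-05 and 0.00283). All 8 basal isolations lay above the upper mean for each of these 9 genes. The auxin response gene PttIAA4 fell by 1.93 ± 0.24 and PTD by 1.08 ± 0.23 (adjusted p = 6.1e-07 and 0.000402). The clone oligos M118F07 and UM43TE12 rose by 3.31 ± 0.18 and 1.76 ± 0.12, and R74E10 fell by 3.83 ± 0.33 and R07C07 fell by 2.81 ± 0.15.

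By list, both photoperiod genes rose, PTCO12 by 0.79 ± 0.13 (adjusted p = 2.1e-05), which is 2 of 2 adjusted over the list alone. Of the light receptors PTCRY1D and PHYB2 rose and PHYB1 (0.34 ± 0.16) and PHYA (0.00 ± 0.24) did not pass, 2 of 4 adjusted over the list alone, with a camera adjusted p of 0.301 and an adjusted p of 0.567 with an estimated correlation. GA20-OX, a gene of gibberellin synthesis, rose by 0.96 ± 0.30 (adjusted p = 0.0116), PTLF by 0.45 ± 0.12 (adjusted p = 0.00529) and PTAG2 by 0.70 ± 0.23 (adjusted p = 0.0156), each 1 member of its list, also when adjusted over the list alone. PTCO12, GA20-OX, PTLF and PTAG2 were named as list members, since their differences did not share a sign in every month and age. PttGA2-OX differed by -0.40 ± 0.20, PTAG1 by -0.26 ± 0.31, PTAP1-1B by -0.25 ± 0.32 and PTAP1-2A by 0.11 ± 0.39, and none of these 4 passed. At age 5 alone PttGA2-OX was at -0.84 ± 0.29, and within hybridisation sets at that age at -1.10 ± 0.34. It passed limma's test after median centring (-0.45 ± 0.17), with wells as separate arrays (-0.42 ± 0.16) and in the compared groups alone (-0.40 ± 0.15), with adjusted p = 0.0376, 0.0216 and 0.0461. Camera gave floral meristem identity an adjusted p of 0.847, and of 0.869 with an estimated correlation. Without the May tips of age 6 PTAG2 was at 0.48 ± 0.27 (adjusted p = 0.138). At age 5 alone PTAG2 was at 0.18 ± 0.34 and PTLF at 0.18 ± 0.18 (adjusted p = 0.699 and 0.436), and within hybridisation sets at that age at 0.21 ± 0.38 and 0.37 ± 0.21 (adjusted p = 0.658 and 0.176). Without the June tips of age 5, GA20-OX (0.31 ± 0.33) and PTID1L3 (0.60 ± 0.27) did not pass (adjusted p = 0.501 and 0.0875), and PTLF was at 0.73 ± 0.13. With the hybridisation set as a fixed term GA20-OX (0.52 ± 0.55), PTID1L3 (0.77 ± 0.48), PHYB2 (0.66 ± 0.25) and PTAG2 (0.74 ± 0.39) did not pass (adjusted p = 0.516, 0.241, 0.0546 and 0.173). In all 100 oligos were called, 63 higher and 37 lower in basal tips, against 51 and 46 in the values as deposited and 47 and 48 after median centring, with the median oligo at 0.12, -0.02 and -0.03. The fit within hybridisation sets at age 5 keeps 1 basal isolation in each month and 1 June upper isolation, so its values are tentative.

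**Figure D3:**
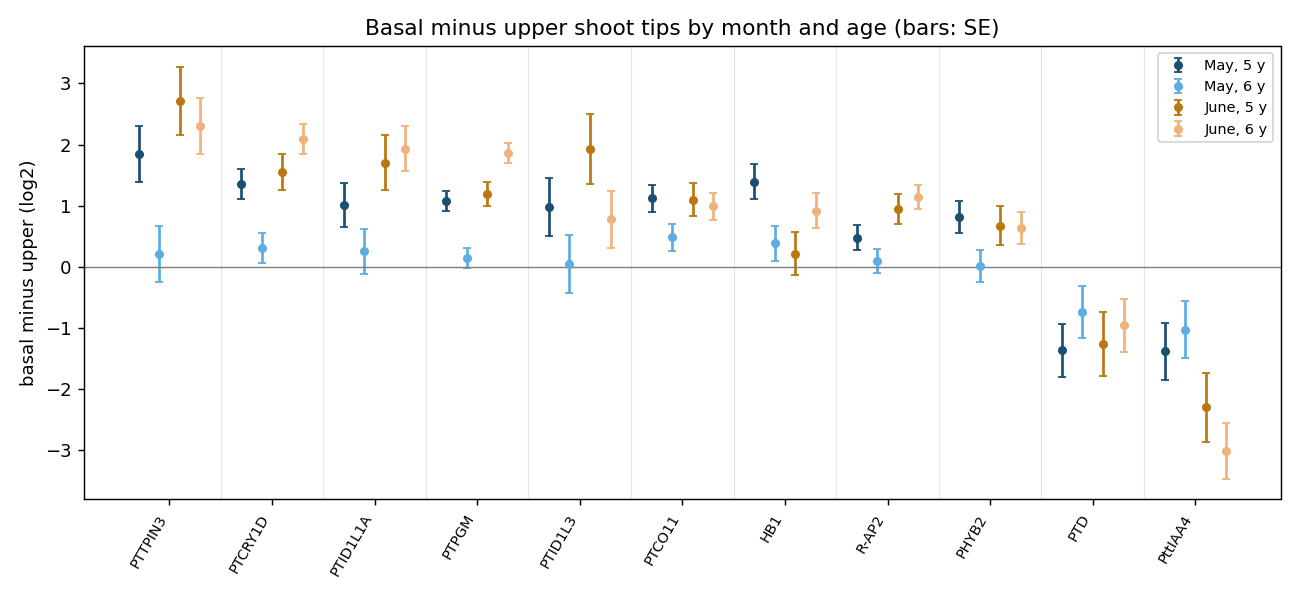
Basal minus upper difference (log2, vertical axis) of the 9 named genes that rose and the 2 that fell most (horizontal axis), with points for May and June at ages 5 and 6 and bars for the SE. PTPGM lies at 1.08, 1.19 and 1.86 in May age 5, June age 5 and June age 6, and at 0.14 in May age 6.

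The basal difference was larger in June for GA20-OX by 1.97 ± 0.60, PTTPIN3 by 1.48 ± 0.49, the phytochrome PHYA by 1.34 ± 0.48 and PTID1L1A by 1.19 ± 0.39, and more negative for PttIAA4 by -1.45 ± 0.49 (adjusted p = 0.0201, 0.0307, 0.0443, 0.0297 and 0.0345, n = 15 isolations). Among clone oligos M118F07 differed by 2.71 ± 0.37, C036P25U by 1.70 ± 0.21, R74E10 by -3.95 ± 0.67 and F098P59Y by -2.43 ± 0.50. For this difference 53 oligos were called, 30 positive and 23 negative (28 and 31 as deposited, 17 and 34 after median centring, with the median oligo at 0.05, 0.02 and -0.11). With both months compared at age 5 alone, 19 oligos were called, and none of the 5 genes named above passed, with adjusted p from 0.0896 to 0.543. There GA20-OX (2.42 ± 0.90) and PHYA (2.03 ± 0.71) were larger, and PTTPIN3 (0.86 ± 0.73), PTID1L1A (0.69 ± 0.58) and PttIAA4 (-0.91 ± 0.73) smaller. M118F07 did not pass there either, at 1.33 ± 0.55 (adjusted p = 0.149). At age 6 alone, without the single June isolation of age 5, GA20-OX (1.52 ± 0.80) and PHYA (0.64 ± 0.64) did not pass (adjusted p = 0.164 and 0.478). There PTTPIN3, PTID1L1A, PttIAA4 and M118F07 passed at 2.09, 1.68, -1.98 and 4.10, with 55 calls. At that age basal and upper tips share no hybridisation set in either month. Nor over both ages did any of the 5 pass with the hybridisation set as a random block (adjusted p from 0.0529 to 0.112), although the differences hardly moved, at 1.90 ± 0.68, 1.45 ± 0.55, 1.30 ± 0.54, 1.24 ± 0.44 and -1.27 ± 0.54 for GA20-OX, PTTPIN3, PHYA, PTID1L1A and PttIAA4. With the set as a fixed term (adjusted p from 0.158 to 0.948, 21 calls) they were at 1.49 ± 1.10, 1.33 ± 0.92, 0.85 ± 0.76, 1.57 ± 0.72 and -0.10 ± 0.84 in the same order. The number called in basal against upper tips was 73 in May at age 5, 10 in May at age 6, 55 in June at age 5 and 86 in June at age 6. On a score of 0 for June upper and 1 for June basal tips, May upper tips lay at 0.67 at age 6 and 0.07 at age 5. May upper tips of ages 1 and 6 differed from ages 2 and 5 by 1.71 for PTTPIN3, 0.92 for PTID1L1A and -1.28 for PttIAA4. Each difference had the sign of the basal difference. The month differences of these genes thus rest in part on the May upper tips of age 6. The 10 in May at age 6 became 7 and 4 without isolation a or b of the basal tips, and 3 and 6 without isolation a or b of the upper tips. Leaving out single isolations ended the call of GA20-OX in 3 of 14 fits, PTTPIN3 in 8, PHYA in 10, PTID1L1A in 7 and PttIAA4 in 7, with adjusted p up to 0.0545, 0.0796, 0.120, 0.0709 and 0.0984. The other settings fixed beforehand ended that of PTTPIN3 in 2 of 7, PHYA in 2 of 6 and PttIAA4 in 1 of 7, with adjusted p up to 0.146, 0.0559 and 0.0525. GA20-OX and PHYA were among the dim oligos, so the setting that leaves these out did not test them.

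June and May shoot tips were compared at matched ages. The CONSTANS homologs were lower in June, PTCO12 by -1.28 ± 0.13 and PTCO11 by -0.77 ± 0.11 (n = 7 and 8 isolations, adjusted p = 3.1e-07 and 2.6e-05). The auxin response genes PttIAA1 and PttIAA6 fell by 0.86 ± 0.10 and 0.73 ± 0.18, and all 7 June isolations lay below the May mean for PTCO12, PTCO11, PttIAA1 and PttIAA6 (adjusted p of the last pair 1.3e-06 and 0.00264). That May mean pools ages that differ, so the count is not matched by age. May tips of ages 1 and 6 averaged 13.71 for PTCO12 and 13.88 for PTCO11, against 11.94 and 12.66 at ages 2 and 5. PCEN-L fell by 0.48 ± 0.15, PTPGM by 0.35 ± 0.09 (5 of 7) and PMFT, a relative of MOTHER OF FT, by 0.29 ± 0.11 (adjusted p = 0.0139, 0.00315 and 0.036). PTLF rose by 0.40 ± 0.12 (5 of 7) and PTTPIN2 by 0.92 ± 0.32 (6 of 7), with adjusted p = 0.0144 and 0.0279. The rise of PTLF rests on age 5, with 1 June isolation. It was 0.08, 0.07, 1.43 and 0.00 at ages 1, 2, 5 and 6, and 0.05 ± 0.13 (adjusted p = 0.798) without age 5. There PTTPIN2 (0.84 ± 0.35), PCEN-L (-0.29 ± 0.16), PMFT (-0.24 ± 0.12) and PHYA (-0.45 ± 0.26) did not pass (adjusted p = 0.0685, 0.173, 0.107 and 0.18). The clone oligos UM69TF07 and R74E10 rose by 1.61 ± 0.28 and 1.56 ± 0.33, and M118F07 and G126P33Y fell by 1.14 ± 0.18 and 1.03 ± 0.24.

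By list, both photoperiod genes fell, 2 of 2 adjusted over the list alone. The light receptors PTCRY1D (-0.45 ± 0.13, 5 of 7) and PHYA (-0.70 ± 0.24, 7 of 7) fell and PHYB1 (-0.29 ± 0.16) and PHYB2 (-0.19 ± 0.14, and called at -0.42 ± 0.15 without age 5) did not pass, 2 of 4 adjusted over the list alone, with a camera adjusted p of 0.299 and an adjusted p of 0.567 with an estimated correlation. PTCRY1D and PHYA were named as list members, since their differences did not share a sign at every age. Of floral meristem identity PTLF rose, PTAP1-1B differed by 0.75 ± 0.32 and PTAP1-2A by -0.14 ± 0.39, 2 of 3 adjusted over the list alone, with a camera adjusted p of 0.405 and an adjusted p of 0.567 with an estimated correlation. PTAG1 (-0.43 ± 0.31), PTAG2 (0.29 ± 0.23), GA20-OX (-0.60 ± 0.30) and PttGA2-OX (0.14 ± 0.20) did not pass, over all oligos or adjusted over the list alone. GA20-OX passed in the values as deposited (-0.89 ± 0.29) and after median centring (-0.93 ± 0.29). In all 78 oligos were called, 37 higher and 41 lower in June. June and May upper tips share no hybridisation set. At ages 2, 5 and 6 the basal tips link the sets, and with the set as a term 13 oligos were called against 66 without it, PMFT then at 0.089, PHYA at 0.079 and G126P33Y at 0.65, and PTCO12 at -0.85 ± 0.38 with an adjusted p of 0.193. Of the 15 oligos called and named here, only PttIAA1, PTCO11 and M118F07 passed with that term. PMFT and PHYA did not pass at these ages without it either (adjusted p = 0.0709 and 0.0869). Among the others PTLF (0.96 ± 0.36), PttIAA6 (-0.91 ± 0.55), PCEN-L (-0.84 ± 0.43) and PTPGM (-0.58 ± 0.26) had larger differences than over all ages and a larger SE. PTCRY1D was at -0.43 ± 0.40, and UM69TF07 (1.16 ± 0.54), R74E10 (0.58 ± 0.98) and PTTPIN2 (0.22 ± 0.96) had smaller ones. Only the May basal tips of age 5 link the sets of the June and May tips, through an isolation whose set is uncertain. Leaving out single isolations ended the call of PMFT in 9 of 14 fits, PTTPIN2 in 7 and PHYA in 6, with adjusted p up to 0.0973, 0.0907 and 0.0779. PTTPIN2 and PCEN-L did not pass in a fit to the compared groups alone (adjusted p = 0.121 and 0.0764), nor PTPGM in the values as deposited (0.0578).

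**Figure D4:**
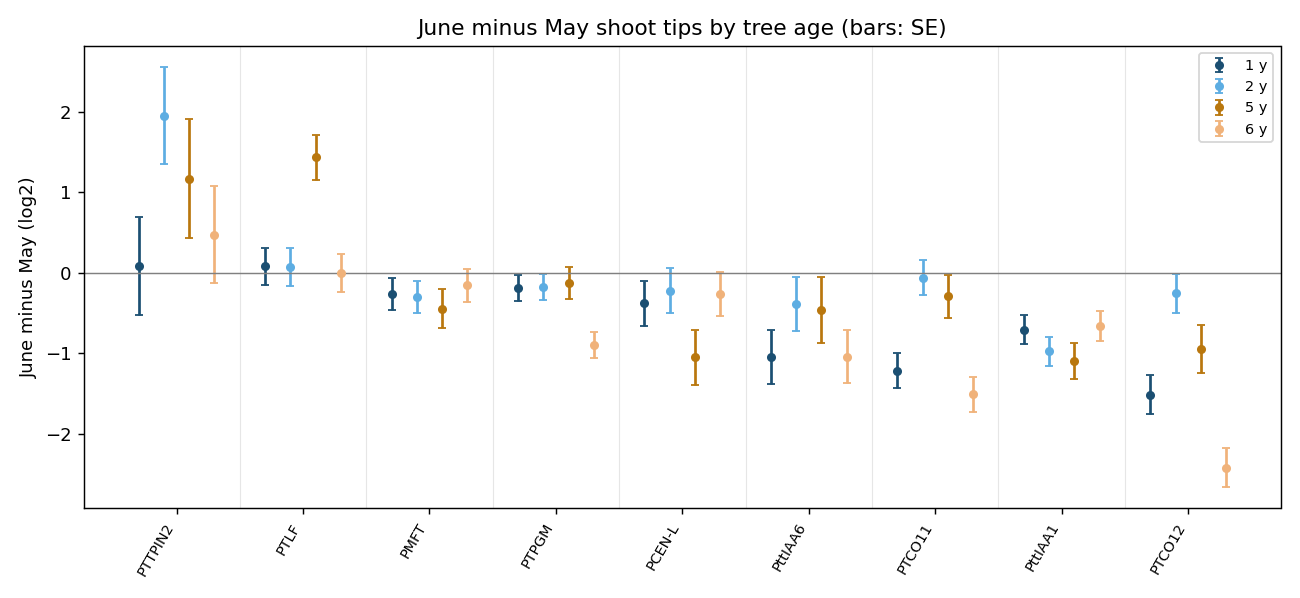
June minus May difference (log2, vertical axis) of the 2 named genes that rose and the 7 that fell most (horizontal axis) in shoot tips, with points for ages 1, 2, 5 and 6 and bars for the SE. PttIAA1 lies between -1.09 and -0.66 at every age, while PTCO12 lies at -1.51 and -2.42 at ages 1 and 6 and at -0.25 at age 2.

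The drop from May to June differed among the 4 ages. The June tips of age 1 lie in a hybridisation set apart from the other June tips, so age and set differ together there. PTCO12 changed by -1.51 ± 0.24 at age 1 and -2.42 ± 0.24 at age 6, against -0.25 ± 0.24 at age 2 and -0.95 ± 0.30 at age 5, and PTCO11 by -1.21, -1.51, -0.06 and -0.29 in the same order. PttIAA1 fell at each age, by 0.70, 0.97, 1.09 and 0.66 at ages 1, 2, 5 and 6. The month comparison called 24, 21, 13 and 67 oligos at ages 1, 2, 5 and 6, and a limma F test for a difference among the 4 ages called 49 oligos. Leaving out an isolation gave 13 to 16, 4 to 10, 7 to 10 and 41 to 59 at ages 1, 2, 5 and 6, lowest without isolation b of June or May at age 1 and isolation a of May at the other ages, and the 49 became 32 without isolation a of the May tips of age 6. With ages 2 and 5 only, June against May gave 43 called oligos, PTCRY1D was at 0.071, and PTCO11 was at -0.18 with an adjusted p of 0.47. The other calls lost there among the named oligos were PttIAA6 (-0.42 ± 0.26), PTPGM (-0.15 ± 0.13), R74E10 (0.03 ± 0.50), M118F07 (-0.30 ± 0.27), PMFT (-0.37 ± 0.16), UM69TF07 (1.07 ± 0.42), G126P33Y (-0.73 ± 0.36) and PHYA (-0.63 ± 0.36), with adjusted p from 0.0732 to 0.962. The planned contrast of the older with the younger pair of ages called 4 oligos, all 4 negative, against 2 positive and 5 negative in the values as deposited and 3 and 5 after median centring. UM43TE12 differed by -1.17 ± 0.24 and V021F11 by -1.03 ± 0.19 (adjusted p = 0.00652 and 0.00292). V021F11 did not pass with wells as separate arrays (-1.03 ± 0.72, adjusted p = 0.558). Neither passed in a fit to the compared groups alone (adjusted p = 0.139 for UM43TE12 and 0.0884 for V021F11). PTCO12 (-0.80 ± 0.26), PTIR1 (-1.61 ± 0.56), PTLF (0.64 ± 0.25), R-AP2 (0.52 ± 0.21) and PTCRY1D (-0.57 ± 0.26) did not pass (adjusted p = 0.102, 0.137, 0.201, 0.238 and 0.325), though PTCO12 and PTLF, as 1 of 2 photoperiod and 1 of 3 floral meristem identity genes, passed adjusted over the list alone. R-AP2 passed limma's test in the values as deposited (0.75 ± 0.20, adjusted p = 0.0353) and after median centring (0.78 ± 0.20, adjusted p = 0.0214). Without isolation a or b of the June tips of age 2 this count was 9 and 9, and without isolation b of the May tips of age 5 it was 7. Without age 5 among the older trees, whose June group has 1 isolation, it was 40, with UM43TE12 at -2.41 ± 0.27, V021F11 at -1.46 ± 0.21, and PTCO12 (-1.53 ± 0.30) and PTCRY1D (-1.36 ± 0.30) also called (adjusted p = 0.00199 and 0.00508). PTLF was then at -0.07.

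Vegetative buds were last compared with May shoot tips at matched ages. PTAP1-1B was higher in buds by 2.45 ± 0.30, PTTPIN2 by 1.80 ± 0.30, PTBF1 by 1.61 ± 0.16 and PTID1L1A by 1.41 ± 0.18 (n = 8 and 8 isolations, adjusted p = 2.6e-07, 1.9e-05, 1.4e-08 and 6.0e-07). PTTPIN3 was lower by -3.50 ± 0.23, PttIAA1 by -2.39 ± 0.09, PttIAA4 by -2.31 ± 0.23 and PMFT by -0.97 ± 0.10 (adjusted p = 1.6e-11, 1.5e-15, 1.1e-08 and 1.6e-08). The clone oligos UM89TG10 and M104E08 rose by 4.18 ± 0.33 and 3.42 ± 0.24, and A009P50U and R26F09 fell by 2.39 ± 0.15 and 2.38 ± 0.10. All 8 bud isolations lay on the same side of the May mean for each of these 12 oligos. Of floral meristem identity 3 of 3 rose and of photoperiod genes 2 of 2 fell, the same counts adjusted over the list alone. PTAP1-2A in buds averaged 4.33 at ages 1, 2 and 5 and 9.31 at age 6, so its rise rests on the buds of age 6. Of 16 oligos higher in male floral buds, 4 were called higher and 1 lower in those buds than at the other ages. In all 131 oligos were called, 71 higher and 60 lower in buds, against 68 and 70 in the values as deposited and 51 and 84 after median centring, with the median oligo at 0.00, -0.01 and -0.17. Organ, season and the label of the tree differ together here, and with the hybridisation set as a term, which rests on the same uncertain isolation, 14 oligos were called. Then 7 of these 12 oligos did not pass, namely PTAP1-1B (1.64 ± 1.33), PTTPIN2 (1.91 ± 1.28), PTBF1 (0.35 ± 0.57), PTID1L1A (1.08 ± 0.81), PttIAA4 (-2.12 ± 0.95), PMFT (-0.37 ± 0.42) and M104E08 (3.32 ± 1.08), with adjusted p of 0.448, 0.352, 0.778, 0.417, 0.153, 0.61 and 0.0677. The differences of PTTPIN2, PttIAA4 and M104E08 stayed about as large while the SE grew, and those of PTBF1 and PMFT shrank.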

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

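The tests of explanations, the splits of the samples, the test among all 4 ages and the settings with hybridisation sets or subsets of ages in this part were chosen after the results were seen, while the tests of differences between organs, of the basal difference by month and of the month difference between older and younger trees were planned.

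Age acted differently in different organs. The F test for a difference of the age contrasts among vegetative buds, May tips and June tips called 48 oligos, with adjusted p of 6.4e-05 for PTCO12, 0.000121 for PttIAA1, 0.000432 for PTBF1, 0.00303 for R-AP2, 0.0039 for PTCO11, 0.0067 for PttIAA6 and 0.0186 for PTLF. The CONSTANS homologs fell with age in vegetative buds, by 1.58 for PTCO12 and 1.19 for PTCO11, and neither was called in shoot tips over all oligos. In June tips they differed by -0.56 and -0.44, and both passed adjusted over the list alone. In May tips PTCO12 stood at 13.50 and 13.91 at ages 1 and 6 and at 11.91 and 11.98 at ages 2 and 5. Of 100 splits of the 23 isolations 1, the real split, gave as many calls, and the highest other split gave 44. Most of these splits part isolations of the same group, which the real split never does, so chance cannot be excluded. The June tips of age 1 lie alone in their hybridisation set, which the test did not adjust for.

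The basal difference differed between months in a test that called 53 oligos, with June minus May differences of 1.97 for GA20-OX, 1.48 for PTTPIN3, 1.34 for PHYA, 1.19 for PTID1L1A and -1.45 for PttIAA4. For the clone oligos the values were 2.71 for M118F07, 1.70 for C036P25U, -3.95 for R74E10 and -2.43 for F098P59Y. None of the 5 genes with a gene-like name passed at age 5 alone (19 calls, adjusted p from 0.0896 to 0.543) or with the hybridisation set as a random block or a fixed term (21 calls with the fixed term). With the random block the differences hardly moved while the SE grew, from 0.60 to 0.68 for GA20-OX at 1.90. At age 5 alone GA20-OX (2.42) and PHYA (2.03) were larger than over both ages, and PTTPIN3 (0.86), PTID1L1A (0.69), PttIAA4 (-0.91) and M118F07 (1.33, adjusted p = 0.149) were smaller, while at age 6 alone GA20-OX (1.52) and PHYA (0.64) did not pass. At age 6 alone PTTPIN3, PTID1L1A, PttIAA4 and M118F07 passed, with larger differences than over both ages, but basal and upper tips share no hybridisation set there. With the fixed term PttIAA4 was at -0.10 and PHYA at 0.85, so the values of all 5 genes are tentative. Of 100 splits of the 15 isolations 3 gave as many calls as the real one, itself included. The highest other split gave 71, more than the real 53, and another, which parted no group, gave 66. Most splits part isolations of the same group, which the real split never does, so this share cannot exclude chance. A count of this size is not specific to this contrast. The month difference between older and younger trees called 4 oligos, among them UM43TE12 at -1.17 and V021F11 at -1.03, neither called in a fit to the compared groups alone, but 40 without age 5, whose June tips are 1 isolation. There 16 of 100 splits of the 15 isolations gave as many calls and the highest other split gave 66, so chance cannot be excluded, and a split with many times the real count points to another structure of these samples. A test among all 4 ages, added after the data were examined, called 49 oligos for the month difference, and fewer without isolation a of the May tips of age 6. Whether the split with 66 calls follows the ages was not tested.

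The May upper tips of ages 1 and 6, which enter both month results, differed from those of ages 2 and 5 in 75 oligos, 45 higher and 30 lower, although all 8 isolations lie in a single hybridisation set, so a difference between these sets is argued against. The sets were inferred from well differences, so other batches that the labels do not give are not covered. The May upper tips of ages 1 and 6 resembled basal tips, since 50 of the 75 were also called between June basal and upper tips and 47 of these had the same sign, where 17.6 would be expected. On a score that is 0 for June upper tips and 1 for June basal tips of ages 5 and 6, they lay at 0.62 to 0.68, against 0.06 to 0.20 for May ages 2 and 5 and 0.78 to 0.84 for May basal tips. Vegetative buds of ages 1 and 2 scored 0.66 and 0.68, so such a score is not specific to basal tips. An exchange of labels between upper and basal tips of age 6 is argued against, since the May basal tips of age 6 scored 0.804 and those of age 5 scored 0.827. Basal tissue collected with the tips may be the source and cannot be told apart from a state shared with basal tips, because only 4 of the 75 oligos lay past the May basal level, about the 3.75 false calls allowed, and a difference in growth stage at ages 1 and 6 stays open and was not tested.

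June tips differed from May tips while sharing no hybridisation set with them, so the set was added as a term at ages 2, 5 and 6. Over the 66 oligos called there, the differences with that term had a slope of 0.968 on those without it, but the offset between the sets rests on 1 group, the May basal tips of age 5, and on isolation b of it, whose well differences correlate at 0.109 with the set it was placed in and at 0.0781 with that of the May tips, so set and month cannot be told apart. The calls fell to 13, of which 9 were called both ways with the same sign, as the median SE went from 0.18 to 0.42, and 56 of 66 kept their sign. PTCO11 and PttIAA1 remained called in that fit, and PTCO12 did not, at -0.85 with an adjusted p of 0.193. Seasonal change in the growing tips stays open as a biological explanation, beside the structure of the May tips by age, and was not tested.

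Among technical measures, array b2 of the vegetative buds of age 5 gave a value for 215 oligos where the other 3 arrays gave 213. Array b1 of the June basal tips of age 6 gave a value for 213 where the others gave 215. Over the 36 groups of values tested, 1.8 such arrays would be expected by chance.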

How the results depend on the processing

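The alternatives with hybridisation sets and subsets of ages were chosen after seeing the data, the others were planned. Of 1070 values of named genes under the settings fixed beforehand, other than leaving out an isolation, 1016 kept direction and side of the threshold, 39 lost and 15 gained a call, and 0 reversed. Leaving out an isolation gave 1792 kept, 122 lost, 18 gained and 0 reversed of 1932, and the added alternatives 534 kept, 84 lost, 5 gained and 7 reversed of 630. With the isolation letter as a block every count stayed within 1.5 times its value, as 64 for floral against vegetative buds, 61 for age in vegetative buds, 99 for basal against upper shoot tips and 76 for June against May shoot tips, but letters do not pair isolations across groups (median correlation -0.0096). The cause of each change below was not tested, except that fewer isolations and fewer residual degrees of freedom enter the fits to the compared groups alone, to 1 set or to fewer ages. The list call of floral meristem identity held with both correlations. Signal over background was not available to set a limit on dim oligos.

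As deposited, male against unstated vegetative buds gave 0 calls, the month difference by age 7 and June against May at age 2 39. With median centring the counts were 0, 8 and 50, and 9 for age in May tips. Without the dimmest oligos male vegetative buds gave 13, the month difference by age 8 and basal tips in May at age 6 6. With wells separate the floral difference by tree type gave 1, male vegetative buds 18, age in May tips 22, June against May at age 5 20 and basal tips in May at age 6 17. With only the compared groups male vegetative buds gave 1, age in May tips 2 and in June tips 2, the month difference by age 0, June against May 13, 0 and 0 at ages 1, 2 and 5, and basal tips in May at age 6 0. A trended robust variance gave 12 for male vegetative buds and 8 for the month difference by age.

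With the set as a random block June against May at age 2 gave 9. With the set as a fixed term the basal difference by month gave 21, vegetative buds against May tips 14, June against May 3, 3 and 39 at ages 2, 5 and 6, and basal tips 2 in May and 45 in June at age 6, the last 40 with isolation b of the May basal tips of age 5 moved to the set of the May tips. Over ages 2, 5 and 6 June against May gave 13, and PMFT (0.089), G126P33Y (0.65) and PHYA (0.079) reversed. Within set 1 male vegetative buds gave 0, and within set 3 age in June tips gave 1. With age 5 alone against ages 1 and 2 PTAP1-2A reversed to -0.46 in vegetative buds, and across organs to -0.000707 without the age 6 vegetative buds. With ages 2 and 5 only June against May gave 43 and PTCRY1D reversed to 0.071, and at age 5 only the basal difference by month gave 19. Without the June tips of age 5 the month difference by age gave 40, and F100P70Y reversed to -0.11 with age in June tips.

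Leaving out each isolation in turn, where a lone isolation left in a group is assumed to vary like the other groups, gave these ranges of calls. Floral against vegetative buds had 44 to 57, its difference by tree type 0 to 2, male against unstated buds 0 to 4 (vegetative) and 0 to 13 (floral). Age gave 51 to 74 in vegetative buds, 3 to 14 in May tips, 15 to 20 in June tips, 42 to 58 across organs and 41 to 54 for the difference between organs. Basal against upper tips gave 92 to 102, its difference by month 40 to 52, and by part 58 to 80 and 3 to 7 in May, and 42 to 51 and 64 to 77 in June, at ages 5 and 6. June against May gave 65 to 79, and 13 to 16, 4 to 10, 7 to 10 and 41 to 59 at ages 1, 2, 5 and 6, with 3 to 9 for the difference between older and younger trees and 32 to 48 among the 4 ages. Vegetative buds against May tips gave 122 to 133. The June tips of age 5, with 1 isolation, could not be left out.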

Other observations

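The tests of explanations in this part, the splits of the samples, the list of auxin genes, the oligo UB18CPG04 and the bud scores were chosen after the results were seen.

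The auxin genes, 5 Aux/IAA response genes and 3 PIN efflux carriers, moved apart rather than together. In floral against vegetative buds 3 of 8 rose and 2 fell, in basal against upper tips 3 rose and 1 fell, in June against May tips 1 rose and 4 fell, and in vegetative buds against May tips 2 rose and 4 fell. The carrier PTTPIN3 changed with position and organ, higher by 1.77 ± 0.24 in basal tips and lower in vegetative buds than in May tips by -3.50 ± 0.23. Unlike it, PTTPIN2 was higher in vegetative buds than in May tips by 1.80 ± 0.30, and PTTPIN1 and PTTPIN2 differed by 0.29 ± 0.20 and -0.02 ± 0.32 between basal and upper tips (adjusted p = 0.261 and 0.964). PttIAA2 rose in basal tips by 0.87 ± 0.15 (adjusted p = 2.7e-05) and fell from May to June by 0.52 ± 0.15 (adjusted p = 0.00767). PttIAA5 passed in none of the floral, basal and month comparisons, with an unadjusted p of 0.7, 0.244 and 0.0564. Camera gave the list adjusted p of 0.553 in each of the floral and basal comparisons and 0.424 for June against May, and 0.712 in all 3 with an estimated correlation.

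The clone oligo UB18CPG04 followed both maturation and organ. It rose with age in vegetative buds, May tips and June tips by 1.71, 1.64 and 0.72, and was lower in floral than in vegetative buds of age 6, by -2.02 ± 0.19 in trees of unstated sex and -2.34 ± 0.19 in male trees. The June tips of age 1 lie alone in their hybridisation set, so the June rise is in part a contrast between sets. UB18CPG04 was also lower in basal than in upper tips in both months and at both ages, by -1.91, -1.38, -1.62 and -0.82 for May age 5, May age 6, June age 5 and June age 6 (adjusted p = 1.8e-08, 4.5e-05, 7.7e-06 and 0.00106). Its level in floral buds of age 6, 8.41 ± 0.28 (SD, n = 2 isolations) in trees of unstated sex, was close to the 8.41 ± 0.03 of vegetative buds at age 1. On the score for basal tips, vegetative buds lay at 0.66, 0.68, 0.90 and 0.84 at ages 1, 2, 5 and 6, and floral buds at 0.89, so a high score is not specific to basal tips.

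Of 16 oligos higher in male floral than in male vegetative buds, 4 were higher in vegetative buds of age 6, 1 was lower and 11 did not pass, 8 of these with a positive and 3 with a negative difference. Compared with ages 1, 2 and 5, PTAP1-2A was higher by 4.98 ± 0.60, M129E09 by 2.31 ± 0.36, PTAP1-1B by 2.00 ± 0.49 and PTLF by 0.76 ± 0.19, PttIAA1 fell by 0.69 ± 0.15, and in male vegetative buds the isolations lay at 9.29 and 5.83 for PTAP1-2A. A difference between hybridisation sets is argued against, since the lower of the age 6 isolations, which lie in different sets, exceeded the highest younger one by 4.09. Floral bud tissue mixed in may account for part of the pattern, since a share of 4.34%, set from PTAP1-2A, predicts a mean rise of 1.35 in 6 other oligos and the observed mean was 1.35 ± 0.19 (SE). However, PTAP1-2A lies near the top value of quantile scaling in floral buds, so this share depends on the scaling. A share of 5.58% set from M129E09 predicts 1.43 in the other 5 against 1.16 ± 0.22. The SE of each mean treats the oligos as independent, although all were measured in the same isolations. It may thus understate the spread. For PTLF the share of 4.34% predicts 0.16 against the 0.76 observed. An early step towards flowering within vegetative buds of 6-year-old trees stays open as well and was not tested.

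Splits of the samples were used to ask whether chance can give as many calls. For floral against vegetative buds 1 of 35 splits, the real split, gave 64 calls and the highest other gave 34. For age in vegetative buds 1 of 35 gave 64 and the highest other gave 22. The real split also gave the most calls for age in June tips (1 of 35 splits, 17 calls, highest other 13), age across organs (1 of 100 splits, 53 calls, highest other 8) and basal against upper tips (1 of 100, 100 calls, highest other 50). The same held for June against May tips (1 of 100, 78 calls, highest other 51) and vegetative buds against May tips (1 of 100, 131 calls, highest other 83). Most other splits part isolations of the same group, which the real split never does, so these counts cannot exclude chance. With ages kept whole, vegetative buds gave 64 calls for ages 5 and 6 against the others, 6 for ages 2 and 6, and 15 for ages 1 and 6. June tips gave 17, 2 and 9 in the same order. So few ways of parting whole ages cannot exclude chance either. For age in May tips chance cannot be excluded, since 4 of 35 splits gave at least the 14 calls of the real split. The highest other split there gave 74 calls, several times the real count, which points to the structure of the May tips by age, with 75 oligos called between ages 1 and 6 and ages 2 and 5.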
